A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

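Gene expression was measured in the fission yeast *Schizosaccharomyces pombe* on 6 Affymetrix tiling arrays. A wild-type parent strain and 2 deletion strains, cid14delta and air1delta, were each hybridised on 2 arrays from biological replicates. Per the labels' protocols, cultures grew in rich YES medium at 30 °C, cells were harvested at an optical density of 0.5, and total RNA was extracted with hot phenol. Biotin-labelled, double-stranded target was prepared, so signal from a gene and from an overlapping or antisense gene could not be told apart.

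The authors deposited 1 table with 1 log2 value for each of 5483 annotated features on each array. The log2 scale was inferred from the values, which ran from 2.75 to 14.8 over the 6 arrays. Per the submitters' processing notes, the affy package was used, without a version or role. The background correction, normalization, summary over probes, centring and genome build are not given in the sources used here. Array medians were 9.21 and 9.21 in wild type, 9.27 and 9.28 in cid14delta, and 9.27 and 9.29 in air1delta. All 6 columns of values were used, and no feature was left out of the tests.

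Systematic IDs were matched to a reference gene table (assembly ASM294v3), which served only for names and for the order of neighbouring genes. Of the features, 5348 matched, 11 of them through a synonym, 135 did not match, and 4252 had a gene symbol. No coordinates are given, since the build of the array annotation is not known. Noncoding RNA IDs numbered 474.

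Strains were compared with limma 3.58.1 in R 4.3.3. A linear model with the strain as the only factor was fitted to all 6 arrays, with 3 residual degrees of freedom, and empirical Bayes moderation added 2.51 prior degrees of freedom. All adjusted p-values of features are from this two-sided limma test with Benjamini-Hochberg adjustment over all features, and a feature was called at an adjusted p under 0.05. The errors of log2 changes are standard errors of the model. With 2 arrays per strain the number of arrays limits the precision, and the spread of each comparison rested on the arrays of all strains.

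Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with the other features. The p-values were adjusted over lists and both mutants together, and separately for the comparison of the mutants with each other. The camera test with an estimated correlation and limma's fry were run beside it. The fry test asks whether a list moves, on balance, in 1 direction, and its mixed form whether it changes in either direction; neither compares a list with other genes. The 26 lists covered RNA tailing and exosome factors, heterochromatin and RNAi factors, subtelomeric genes, the mating-type locus, Tf2 retrotransposons, Mmi1-dependent meiotic mRNAs and genes named mug or meu. They further covered large ribosomal subunit assembly, small subunit and nucleolar factors, ribosomal proteins, small nucleolar and small nuclear RNAs, transfer RNAs, ribosomal RNAs, noncoding RNAs, mitochondrial genes and histones. The last group held stress genes, protein folding, phosphate and thiamine supply, iron and copper supply, nitrogen starvation and mating entry, markers of M and P cells, G1/S genes, septation genes and auxotrophic marker genes. The mating-type, transfer RNA, ribosomal RNA and mitochondrial lists had 0 measured members, the small nucleolar and small nuclear RNA list had 1, and the other 21 lists were tested. The symbols ssf1, krr1 and kre33 were not matched. The patterns for ribosomal proteins and for small nuclear RNAs were narrowed after feature results were seen and before list results were computed, because they had caught proteins of other functions. The genes cid14 and air1 were left out of every list.

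The genes to be named were set by rule before the data were examined, as were the comparisons, the lists and most alternatives. For each mutant against wild type the rule took the deleted gene, then the 12 largest rises and the 12 largest falls among called features whose mutant arrays both lay on the same side of both wild-type arrays. Between the mutants it took 6 and 6, and from each list up to 4 members with the smallest p. The rule passed over features without a gene name. This was read as features not matched to the reference table, a reading settled after values had been seen, so matched features that have only a systematic ID are named.

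Per the labels, same-numbered wild-type and cid14delta arrays shared a day, and this day paired them. Deviations of same-numbered arrays from their strain means correlated at r = -0.00632 between wild type and cid14delta, at 0.0413 between wild type and air1delta, and at 0.0159 between the mutants. The array identifiers in the labels put wild type and cid14delta in 1 array series and air1delta in another that held no wild-type array. The design by itself therefore does not separate array series from strain in comparisons of air1delta. Within a strain, the 2 arrays correlated across features at 0.995 in wild type, 0.997 in cid14delta and 0.996 in air1delta. No 2 arrays of a strain had more than 1 feature with identical values.

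The alternatives were centring each array on its median, quantile normalization, leaving out the lowest 0.25 of features, an intensity trend or robust moderation, only the arrays of the strains compared, a change of at least 1 on the log2 scale, an ordinary two-sample test without shrinkage, the replicate number as a block, and leaving out each array. A block by the shared day, a filter at the level of the deleted genes and the removal of a trend with gene length were added after the data were seen, as were the alternatives for the lists between the mutants. The shared-day block was first coded so that air1delta was set against the first day only, which gave 180 features in cid14delta, 555 in air1delta and 3 between the mutants. It was recoded after these counts were seen, with both days weighted equally, which gave 180, 1078 and 68. The highest value of a deleted gene in its own deletion arrays, 4.90, was taken as the level without transcript. The mean of 444 features (8.10%) lay at or below it, among them 312 noncoding RNAs (65.8% of those).

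The procedure was tested on simulated data in which 200 of 5483 features were changed, in 20 draws. Noise was drawn from the fitted limma model, independently for each feature and array. No day, series or array-wide difference was simulated, so the false-call rates hold only for data without them. For cid14delta against wild type it recovered 56.1%, 91.3% and 98.2% of changes of 0.5, 1 and 2 on the log2 scale, with 5.19% false calls. For air1delta against wild type it recovered 56.8%, 91.1% and 98.1%, with 4.67% false calls. The camera test called 2.24% of simulated unchanged lists at an unadjusted 0.05. Those lists held independently drawn features, so this share does not cover lists of correlated genes. The estimated correlation was 0.316 for the large subunit assembly genes. Groups that share control arrays were simulated in 100 draws, also without any day, series or array-wide difference. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

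Several tests of explanations were split, and the rule for reading the growth-rate test was changed, after their first results were seen. The gene families and the features usp103, lsm6, atp14, tlh1 and SPBPB2B2.03c were picked from the values and not by the naming rule.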

Results

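Expression profiles were collected from wild-type fission yeast and from strains lacking cid14 or air1, with 2 arrays per strain from biological replicates and 5483 annotated features per array. Cid14 is a noncanonical poly(A) polymerase and Air1 a zinc-knuckle protein, and both belong to the TRAMP complex, which tags nuclear RNAs for the exosome. Per the series design, each mutant was compared with the parent strain. The number of arrays limits the precision, and the median standard error of a log2 change was 0.08.

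The deleted genes were read first. The log2 values of cid14 (SPAC12G12.13c) were 8.92 and 8.84 in wild type, 3.91 and 3.63 in cid14delta, and 8.996 and 8.95 in air1delta. The values of air1 (SPBP35G2.08c) were 10.49 and 10.40 in wild type, 10.46 and 10.64 in cid14delta, and 4.42 and 4.90 in air1delta. In cid14delta, cid14 fell by 5.11 ± 0.10 (log2 change ± SE, n = 2 arrays per strain), a drop of at least 34.5-fold with an adjusted p of 8.98e-05. In air1delta, air1 fell by 5.78 ± 0.17, a drop of at least 55.1-fold with an adjusted p of 0.00061. Both folds are lower bounds, since the deleted genes' own values were taken as the level without transcript. The change of air1 in cid14delta was 0.11 (adjusted p = 0.699), and that of cid14 in air1delta was 0.09 (adjusted p = 0.53).

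**Figure D1:**
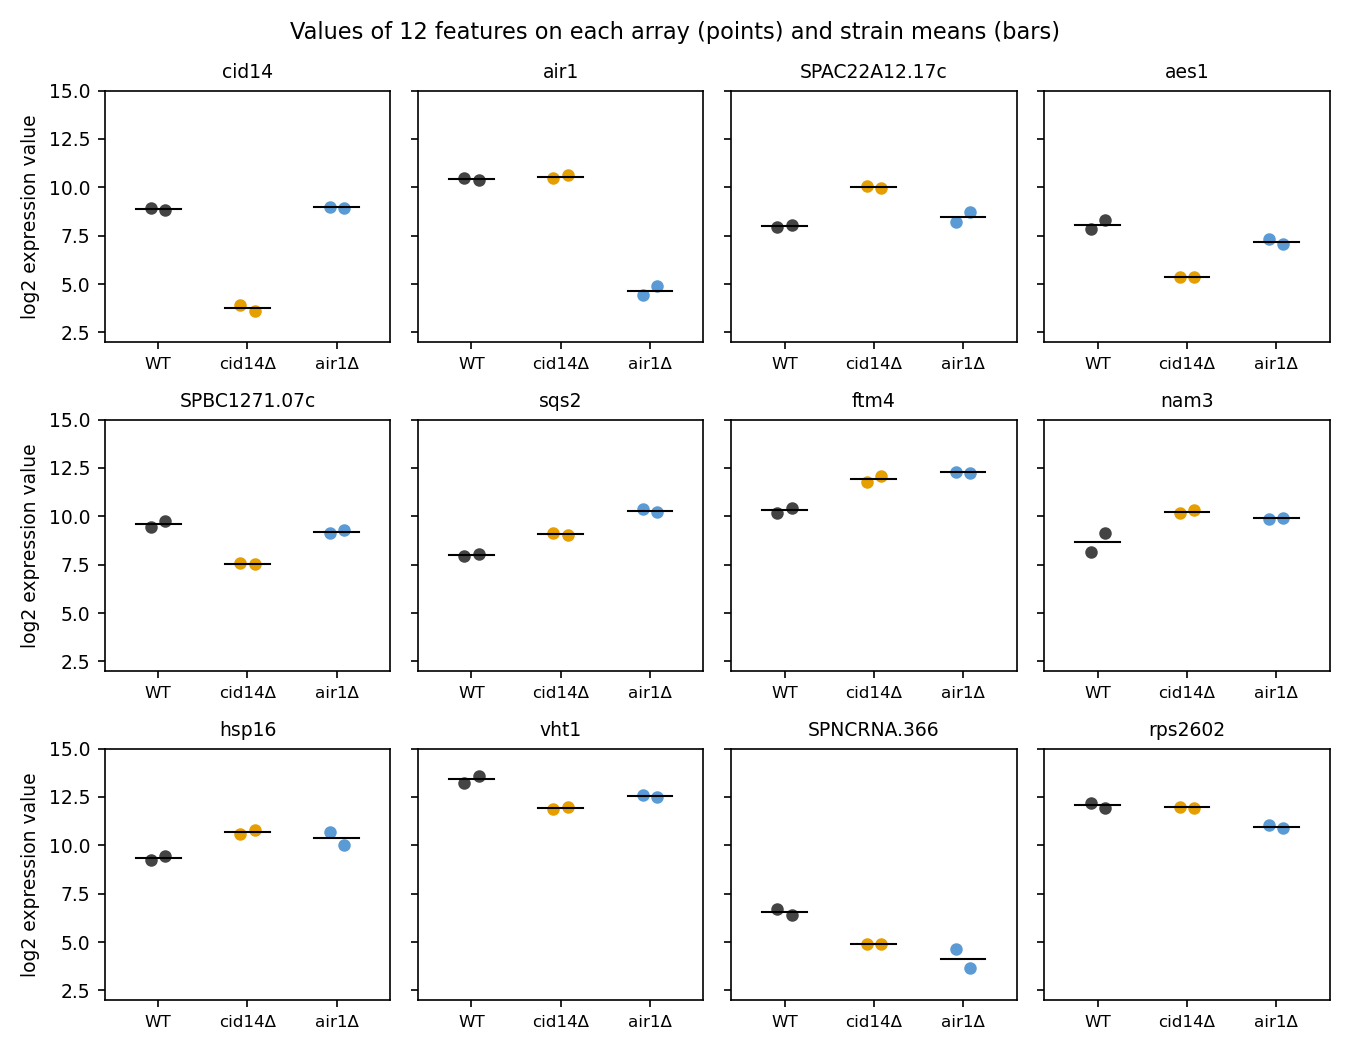
The log2 expression value (vertical axis) of 12 features is plotted for each array (points), with the mean of each strain (bars), n = 2 arrays per strain. The deleted gene cid14 lies at 3.91 and 3.63 in cid14delta and air1 at 4.42 and 4.90 in air1delta, aes1 is lowest in cid14delta, and sqs2 is highest in air1delta.

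The question of which transcripts depend on Cid14 was addressed by comparing cid14delta with wild type. Among features admitted by the naming rule, the largest rises were those of SPAC22A12.17c, which rose by 2.01 ± 0.16 on the log2 scale (4.03-fold, adjusted p = 0.011), and SPBCPT2R1.04c, which rose by 1.99 ± 0.42 (adjusted p = 0.0485). SPAC4H3.08 (1.69 ± 0.12), the subtelomeric ftm4 (SPAC750.05c, 1.64 ± 0.13), the long noncoding RNA nam3 (SPNCRNA.532, 1.59 ± 0.32) and mug125 (SPAC1A6.08c, 1.51 ± 0.09) followed. SPBPB2B2.03c, not matched to the reference table and so outside the rule, rose by 1.97 ± 0.27 (adjusted p = 0.0241). The small heat shock protein gene hsp16 (SPBC3E7.02c) rose by 1.37 ± 0.23 from a mean of 9.33 to 10.70. Further rises were those of SPCC191.05c (1.46), SPBPB2B2.06c (1.37), the pseudogene SPCC18B5.02c (1.30), SPAC144.01 (1.29) and hpz2 (SPAC13F5.07c, 1.28), whose wild-type mean of 4.05 was at the level of a deleted gene, so that its rise is a lower bound.

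After cid14 itself, the largest fall in cid14delta was that of aes1 (SPBPB21E7.07), which fell by 2.7 ± 0.16 (6.50-fold, adjusted p = 0.00665). SPCC70.08c fell by 2.25 ± 0.36 and SPBC1271.07c by 2.06 ± 0.12. The biotin transporter gene vht1 (SPAC1B3.16c) fell by 1.49 ± 0.13 from a mean of 13.40, the guanine deaminase gene gud1 (SPCC1672.03c) fell by 1.33 ± 0.11, and the NAD-dependent glutamate dehydrogenase gene gdh2 (SPCC132.04c) fell by 1.11 ± 0.13. The noncoding RNA SPNCRNA.366 fell by 1.69 or more (adjusted p = 0.04) to 4.88, and the M-factor precursor gene mfm2 (SPAC513.03) fell by 1.10 or more (adjusted p = 0.0231) to 4.64. Both ended at the level of a deleted gene, so these are lower bounds and their rank is not known. SPAC3G6.05 (-1.39), SPAC11D3.18c (-1.35), SPAC227.17c (-1.19) and aca1 (SPAC21E11.04, -1.11) completed the largest falls.

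In all, limma called 475 features in cid14delta (8.66%), 262 higher and 213 lower, with 25 higher and 15 lower by at least 1 on the log2 scale; 1641 passed an unadjusted p of 0.05. With each array centred on its median the split was 190 higher and 355 lower, so that 55.2% higher became 34.9%. The values of both strains did not overlap for 62.7% of features, where chance gives 33.3% if no difference runs across whole arrays. Array medians did differ, at 9.21 and 9.21 in wild type against 9.27 and 9.28 in cid14delta, which by itself raises the share. The count rested on the spread pooled over 6 arrays. It was 69 from the 4 arrays of both strains, 180 with the shared day as a block in 6 arrays, 179 with the replicate number as a block, and 1 with the replicate block in 4 arrays. Without cid14delta replicate 1 or without cid14delta replicate 2 only cid14 itself was called (1 feature each), and without wild type replicate 2 the count was 46. After quantile normalization SPBCPT2R1.04c, nam3, SPBPB2B2.06c, rrp6, rdp1, sir2, mcp7, imp4, rpp203, thi9, yox1, cig2 and adg2 no longer passed the test in cid14delta. With the replicate number as a block, which pairs wild-type and cid14delta arrays by day, 33 of 69 named calls in cid14delta were lost. These were SPBCPT2R1.04c, nam3, hsp16, SPBPB2B2.06c, SPCC70.08c, rrp6, dcr1, rdp1, sir2, mcp7, mug8, mug182, spb1, rpf1, nip7, imp4, rpp202, rps3002, rpp203, rpl3601, gst2, thi9, isp7, isp6, gpa1, ctp1, yox1, cdt2, cig2, eng1, chs2, adg2 and arg3. The shared-day block lost 33 as well, with SPNCRNA.366 in place of nam3.

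Genes for assembly of the large ribosomal subunit lay above the other features in cid14delta. All 27 members had positive changes, with a median of 0.27, and 7 rose, 0 fell and 20 did not pass the test (19 higher and 0 lower adjusted over the list alone). Among them ebp2 rose by 0.52 ± 0.07, spb1 by 0.43 ± 0.07, rpf1 by 0.38 ± 0.06 and nip7 by 0.37 ± 0.06. The camera test gave an adjusted p of 3.23e-07, against adjusted p = 0.641 with an estimated correlation. Of 20 small subunit and nucleolar factors, 2 rose, 0 fell and 18 did not pass (9 and 0 adjusted over the list alone), with gar2 at 0.46 ± 0.07 and imp4 at 0.46 ± 0.08. That list also lay above the other features (adjusted p = 0.00524, and adjusted p = 0.641 with an estimated correlation), but not without wild type replicate 2 (shift 0.09, adjusted p = 0.073). Of 136 ribosomal protein genes, rpp202 (0.63), rps3002 (0.46) and rpl3601 (0.35) rose, rpp203 (-0.34) fell, and 132 did not pass (0 and 0 adjusted over the list alone). Their median was -0.02 as deposited and 0.04 after quantile normalization, a change of sign; the list did not pass as deposited (adjusted p = 0.156) and passed as higher after quantile normalization (adjusted p = 0.0339).

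Septation genes lay below the other features in cid14delta, with a median of -0.16 over 12 members (adjusted p = 0.00307, and adjusted p = 0.641 with an estimated correlation). The endoglucanase gene eng1 (-0.47 ± 0.07), chs2 (-0.38 ± 0.07) and adg2 (-0.33 ± 0.07) fell, 0 rose and 9 did not pass (0 higher and 4 lower adjusted over the list alone). Of 9 biosynthesis genes that often serve as auxotrophic markers, lys1 (-0.70 ± 0.06), arg3 (-0.55 ± 0.09) and leu1 (-0.50 ± 0.06) fell, 0 rose and 6 did not pass (0 and 3 adjusted over the list alone). Their median was -0.24, and the list had an adjusted p of 0.000383, with adjusted p = 0.641 with an estimated correlation. The 17 iron and copper supply genes had a median of -0.24 and lay below the other features (shift -0.51, adjusted p = 0.0277, and adjusted p = 0.641 with an estimated correlation). None of the 17 passed limma's test (0 higher and 0 lower, also adjusted over the list alone), and the iron permease gene fip1 had -1.22 ± 0.38 (adjusted p = 0.103). The list's call was lost with fry (adjusted p = 0.152), after quantile normalization (adjusted p = 0.19), without wild type replicate 2 (shift -0.13, adjusted p = 0.213) and without cid14delta replicate 2 (shift -0.43, adjusted p = 0.0538).

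Among 27 RNA tailing and exosome genes in cid14delta, the nuclear exosome nuclease gene rrp6 rose by 0.39 ± 0.08, 0 fell and 26 did not pass (7 higher and 1 lower adjusted over the list alone; list adjusted p = 0.0751). Of 25 heterochromatin and RNAi genes, dsh1 (0.52 ± 0.08), the Dicer gene dcr1 (0.32 ± 0.06), the RNA-dependent RNA polymerase gene rdp1 (0.37 ± 0.07) and the deacetylase gene sir2 (0.38 ± 0.08) rose, 0 fell and 21 did not pass (7 and 1 adjusted over the list alone; list adjusted p = 0.104). Of 133 subtelomeric genes, 9 rose, 12 fell and 112 did not pass (18 and 14 adjusted over the list alone; list adjusted p = 0.455), with hsp3104 at 0.90 ± 0.07 and SPBPB21E7.09 at -0.83 ± 0.07. Their median was -0.01 and their mean 0.02, and the test pointed down. The Tf2 retrotransposons Tf2-13 (0.21), Tf2-10 (-0.30) and Tf2-11 (0.07) gave 0 calls, also adjusted over the list alone (adjusted p = 0.297 for Tf2-13; list adjusted p = 0.921), and their median was 0.07 and their mean -0.0043 while the test pointed up. Of 474 noncoding RNAs, 15 rose, 15 fell and 444 did not pass (8 and 3 adjusted over the list alone; list adjusted p = 0.156), with SPNCRNA.322 at 0.84 ± 0.07 and SPNCRNA.44 at 0.71 ± 0.06. Of them, 65.8% had a mean at or below the level of a deleted gene.

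Of 17 Mmi1-dependent meiotic mRNAs, mcp7 rose by 1.10 ± 0.21, mug8 fell by 0.41 ± 0.08 and 15 did not pass (1 and 1 adjusted over the list alone; list adjusted p = 0.11). Of 115 genes named mug or meu, 4 rose, 3 fell and 108 did not pass (3 and 1 adjusted over the list alone; list adjusted p = 0.615), with mug2 at 0.97 ± 0.16 and mug182 at -0.35 ± 0.06. Of 18 nitrogen starvation and mating genes, the pheromone receptor gene mam2 rose by 0.65 ± 0.07, isp7 (-0.56), isp6 (-0.45) and gpa1 (-0.33) fell, and 14 did not pass (2 and 5 adjusted over the list alone; list adjusted p = 0.242). Of 7 M-cell markers, mam2 rose, mfm2 fell and 5 did not pass (1 and 1 adjusted over the list alone; list adjusted p = 0.8), and camera pointed down where fry pointed up. The 5 P-cell markers gave 0 calls (0 and 1 adjusted over the list alone; list adjusted p = 0.0751), with sxa1 at -0.24 ± 0.06 (adjusted p = 0.0627). Of their changes 0 were positive, and the list passed as lower after quantile normalization (shift -0.22, adjusted p = 0.0339) and with fry (adjusted p = 0.0236). Of 13 G1/S genes, ctp1 (0.39), yox1 (0.31) and cig2 (0.28) rose, cdt2 (-0.39) fell and 9 did not pass (3 and 4 adjusted over the list alone; list adjusted p = 0.194).

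Of 20 core stress genes in cid14delta, hsp16 and the glutathione S-transferase gene gst2 (0.80 ± 0.14) rose, 0 fell and 18 did not pass (7 and 0 adjusted over the list alone; list adjusted p = 0.0848). The stress list passed as higher after quantile normalization (shift 0.26, adjusted p = 0.0339). Of 14 protein folding genes, hsp16 rose, 0 fell and 13 did not pass (1 and 0 adjusted over the list alone; list adjusted p = 0.574), and the list's mean was 0.09 while its test pointed down. Of 12 phosphate and thiamine genes, tgp1 (0.72 ± 0.12), bsu1 (0.54 ± 0.08) and the thiamine transporter gene thi9 (0.36 ± 0.07) rose, 0 fell and 9 did not pass (3 and 1 adjusted over the list alone; list adjusted p = 0.426). The 11 histone genes gave 0 calls, also adjusted over the list alone (list adjusted p = 0.156), with pht1 at 0.28 ± 0.08 (adjusted p = 0.0822). After quantile normalization the histone list passed as higher (shift 0.17, adjusted p = 0.0165).

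The question of which transcripts depend on Air1 was addressed by comparing air1delta with wild type. Among features admitted by the naming rule, the largest rises were those of sqs2 (SPCC1442.13c), which rose by 2.28 ± 0.09 (4.85-fold, adjusted p = 0.00152), the pseudogene SPCC18B5.02c (2.01 ± 0.10) and ftm4 (1.96 ± 0.13). SPAC977.04 rose by at least 1.91 (adjusted p = 0.0145), a lower bound because its wild-type level was that of a deleted gene, and SPCC191.05c rose by 1.87 ± 0.12. SPBPB2B2.03c, outside the rule, rose by 2.01 ± 0.27 (adjusted p = 0.011). The ubiquitin-like modifier gene ned8 (SPBC12D12.08c) rose by 1.53 ± 0.41 (adjusted p = 0.0451), and wtf25 (SPCC1919.06c), of a family of meiotic drivers, rose by 1.37 ± 0.21. Further rises were those of SPBC23G7.10c (1.69), SPAC27E2.14 (1.63), SPAPB1E7.01c (1.51), SPCC663.08c (1.43) and SPAC5H10.04 (1.32).

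Among admitted features, the noncoding RNA SPNCRNA.366 fell by 2.43 or more in air1delta (adjusted p = 0.0108), a lower bound because it ended at the level of a deleted gene. The gene rps2602 (SPAC1805.11c), which encodes a small subunit ribosomal protein, fell by 1.12 ± 0.10, and gdh2 fell by 1.01 ± 0.13. The vacuolar amino acid transporter gene fnx2 (SPBC3E7.06c) fell by 1.00 ± 0.10 and the histone chaperone gene chz1 (SPAC4G9.06c) by 1.00 ± 0.06. The rhomboid protease genes rbd2 (SPCC790.03, -0.96) and rbd4 (SPAC19B12.06c, -0.92) fell, as did SPAC212.04c (-1.23), SPAC29B12.11c (-1.13), SPBC21B10.02 (-1.13), SPAC11D3.18c (-1.08) and SPCC1795.12c (-1.04).

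In all, limma called 1434 features in air1delta (26.2%), 901 higher and 533 lower, with 53 higher and 12 lower by at least 1 on the log2 scale; 2258 passed an unadjusted p of 0.05. The split was 640 higher and 826 lower after median centring, 616 and 662 after quantile normalization, and 714 and 645 after a trend with gene length was removed. The values did not overlap for 69.05% of features, where chance gives 33.3% if no difference runs across whole arrays. The medians of the air1delta arrays, 9.27 and 9.29, also lay above those of the wild type. The air1delta arrays belonged to another array series than the wild type, so the design by itself does not separate array series from strain. The count was 870 from the 4 arrays of both strains. It was 952 without wild type replicate 1, 535 without wild type replicate 2, 324 without air1delta replicate 1 and 273 without air1delta replicate 2. After quantile normalization SPAC27E2.14, ned8, cid12, mug9, meu32, cnp1, hht3, pyp2, ish1, ssa1, thi9, nmt1, pho1, rep1, mam2, yox1, adg3 and leu1 no longer passed the test in air1delta. With the replicate number as a block, ned8, dim1, pht1, hsp16, map4, cdt2, eng1, his3 and leu1 did not pass, 9 of 90 named calls. The shared-day block lost 10, with SPAC27E2.14, ish1 and ssa1 in place of hsp16 and his3.

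Large subunit assembly genes lay above the other features in air1delta as well, with a median of 0.29 and 25 of 27 changes positive. Of them 15 rose, 0 fell and 12 did not pass (18 and 0 adjusted over the list alone), among them mak16 (0.83 ± 0.11), ebp2 (0.70 ± 0.07), rpf1 (0.55 ± 0.06) and nip7 (0.52 ± 0.06). The camera test gave an adjusted p of 0.000156, and adjusted p = 0.641 with an estimated correlation. Of 20 small subunit and nucleolar factors, 5 rose, 0 fell and 15 did not pass (9 and 0 adjusted over the list alone), with dim1 at 0.68 ± 0.16 and rrp9 at 0.45 ± 0.06. This list had an adjusted p of 0.0277, and adjusted p = 0.641 with an estimated correlation. It was not called without wild type replicate 2 (shift 0.10, adjusted p = 0.122) or without air1delta replicate 1 (shift 0.13, adjusted p = 0.0597).

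Ribosomal protein genes lay below the other features in air1delta, with a median of -0.10. Of 136, 2 rose, 25 fell and 109 did not pass (2 and 19 adjusted over the list alone), with rpl2002 at -0.60 ± 0.06, rps403 at -0.47 ± 0.06 and rpp202 at 0.85 ± 0.10. The camera test gave an adjusted p of 1.18e-06, and adjusted p = 0.641 with an estimated correlation. After quantile normalization the median was -0.02 and the call was lost (shift -0.06, adjusted p = 0.39).

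Of 17 Mmi1-dependent meiotic mRNAs in air1delta, mcp7 (1.14 ± 0.21), mug9 (0.66 ± 0.16), the meiotic kinase gene mek1 (0.64 ± 0.10) and meu32 (0.46 ± 0.12) rose, 0 fell and 13 did not pass (5 and 0 adjusted over the list alone). The list lay above the other features (adjusted p = 0.0442, and adjusted p = 0.641 with an estimated correlation). Most of its members were among the lowest 0.25 of features, and without those too few remained to test the list. Its call was lost with fry (adjusted p = 0.101), after quantile normalization (adjusted p = 0.286), without wild type replicate 2 (shift 0.15, adjusted p = 0.14), without air1delta replicate 1 (shift 0.27, adjusted p = 0.0597) and without air1delta replicate 2 (shift 0.23, adjusted p = 0.113). Of 12 septation genes, adg2 (-0.65 ± 0.07), adg3 (-0.34 ± 0.07) and eng1 (-0.31 ± 0.07) were among 4 that fell, the glucanase gene agn1 (0.35 ± 0.06) rose and 7 did not pass (1 and 4 adjusted over the list alone). This list had a median of -0.14 (adjusted p = 0.0176, and adjusted p = 0.641 with an estimated correlation), and its adjusted p was 0.0538 with the lowest 0.25 of features left out.

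The 17 iron and copper supply genes in air1delta had a median of -0.36. The vacuolar iron transporter gene pcl1 rose by 0.50 ± 0.12, the siderophore transporter gene str2 fell by 0.67 ± 0.12, and 15 did not pass (0 and 1 adjusted over the list alone). The list had an adjusted p of 0.0428, and adjusted p = 0.641 with an estimated correlation. Its call was lost with fry (adjusted p = 0.152), after quantile normalization (adjusted p = 0.286), with the lowest 0.25 of features left out (adjusted p = 0.108), without wild type replicate 2 (shift -0.07, adjusted p = 0.418), without air1delta replicate 1 (shift -0.46, adjusted p = 0.0597) and without air1delta replicate 2 (shift -0.43, adjusted p = 0.0713). Of 9 auxotrophic marker genes, lys1 (-0.48 ± 0.06), his3 (-0.37 ± 0.08) and leu1 (-0.24 ± 0.06) fell, 0 rose and 6 did not pass (1 and 3 adjusted over the list alone; list adjusted p = 0.0506).

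Among 27 RNA tailing and exosome genes in air1delta, 6 rose, 3 fell and 18 did not pass (7 and 4 adjusted over the list alone; list adjusted p = 0.283). The exosome subunit genes rrp41 (0.86 ± 0.12) and csl4 (0.82 ± 0.07) and the nuclease gene rrp6 (0.59 ± 0.08) were among those that rose. Of 25 heterochromatin and RNAi genes, 8 rose, 1 fell and 16 did not pass (10 and 1 adjusted over the list alone; list adjusted p = 0.0744). The RNAi factor genes stc1 (1.05 ± 0.09) and arb1 (0.61 ± 0.09) and the deacetylase gene sir2 (0.60 ± 0.08) rose, and the anti-silencing gene epe1 (-0.45 ± 0.06) fell. Of 133 subtelomeric genes, 24 rose, 9 fell and 100 did not pass (24 and 9 adjusted over the list alone; list adjusted p = 0.258), with mfs2 at 1.09 ± 0.09 and hsp3104 at 0.72 ± 0.07. Of 474 noncoding RNAs, 32 rose, 19 fell and 423 did not pass (9 and 6 adjusted over the list alone; list adjusted p = 0.882), with SPNCRNA.410 at 1.35 ± 0.15 and SPNCRNA.564 at 0.85 ± 0.09. The median and mean of the noncoding RNAs and the test pointed up, while their shift against the other features was -0.0055. The Tf2 retrotransposons gave 0 calls, also adjusted over the list alone (list adjusted p = 0.156), with Tf2-11 at -0.33 ± 0.11 (adjusted p = 0.0831).

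Of 115 genes named mug or meu in air1delta, 14 rose, 7 fell and 94 did not pass (8 and 5 adjusted over the list alone; list adjusted p = 0.284), with mug121 at 1.13 ± 0.11 and mug117 at 0.64 ± 0.08. Of 18 nitrogen starvation and mating genes, 2 rose, 4 fell and 12 did not pass (3 and 4 adjusted over the list alone; list adjusted p = 0.921), with rep1 at 0.40 ± 0.07, isp4 at -0.57 ± 0.10 and isp7 at -0.51 ± 0.09. Their median was 0.11 while the test pointed down. Of 7 M-cell markers, mam2 (0.34 ± 0.07) rose, mam3 (-0.72 ± 0.09) fell and 5 did not pass (1 and 2 adjusted over the list alone; list adjusted p = 0.574). Of 5 P-cell markers, sxa1 (-0.39 ± 0.06) and map4 (-0.38 ± 0.10) fell and 3 did not pass (0 and 2 adjusted over the list alone; list adjusted p = 0.0961). This list too passed as lower after quantile normalization (shift -0.30, adjusted p = 0.0413) and with fry (adjusted p = 0.0236). Of 13 G1/S genes, the DNA end resection gene ctp1 (0.92 ± 0.06), yox1 (0.40 ± 0.06) and the cyclin gene cig2 (0.31 ± 0.06) rose, cdt2 (-0.28 ± 0.08) fell and 9 did not pass (3 and 1 adjusted over the list alone; list adjusted p = 0.574).

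Of 20 core stress genes in air1delta, 5 rose, 0 fell and 15 did not pass (5 and 0 adjusted over the list alone; list adjusted p = 0.201), among them gst2 (0.82 ± 0.14), the glutaredoxin gene grx1 (0.67 ± 0.13) and pyp2 (0.54 ± 0.09). Of 14 protein folding genes, hsp16 (1.02 ± 0.23) and ssa1 (0.81 ± 0.22) rose and 12 did not pass (0 and 0 adjusted over the list alone; list adjusted p = 0.576). The folding list's shift was 0.10 as deposited and 0.23 after quantile normalization, where it passed as higher (adjusted p = 0.0339). Of 12 phosphate and thiamine genes, thi9 (0.34 ± 0.07) and nmt1 (0.32 ± 0.07) rose, the acid phosphatase gene pho1 (-0.36 ± 0.10) fell and 9 did not pass (2 and 1 adjusted over the list alone; list adjusted p = 0.553). Of 11 histone genes, the centromeric histone gene cnp1 (0.39 ± 0.08) and pht1 (0.30 ± 0.08) rose, hht3 (-0.27 ± 0.06) fell and 8 did not pass (2 and 1 adjusted over the list alone; list adjusted p = 0.757). The histone median was -0.01 and the mean 0.02, and the camera test pointed down.

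**Figure D2:**
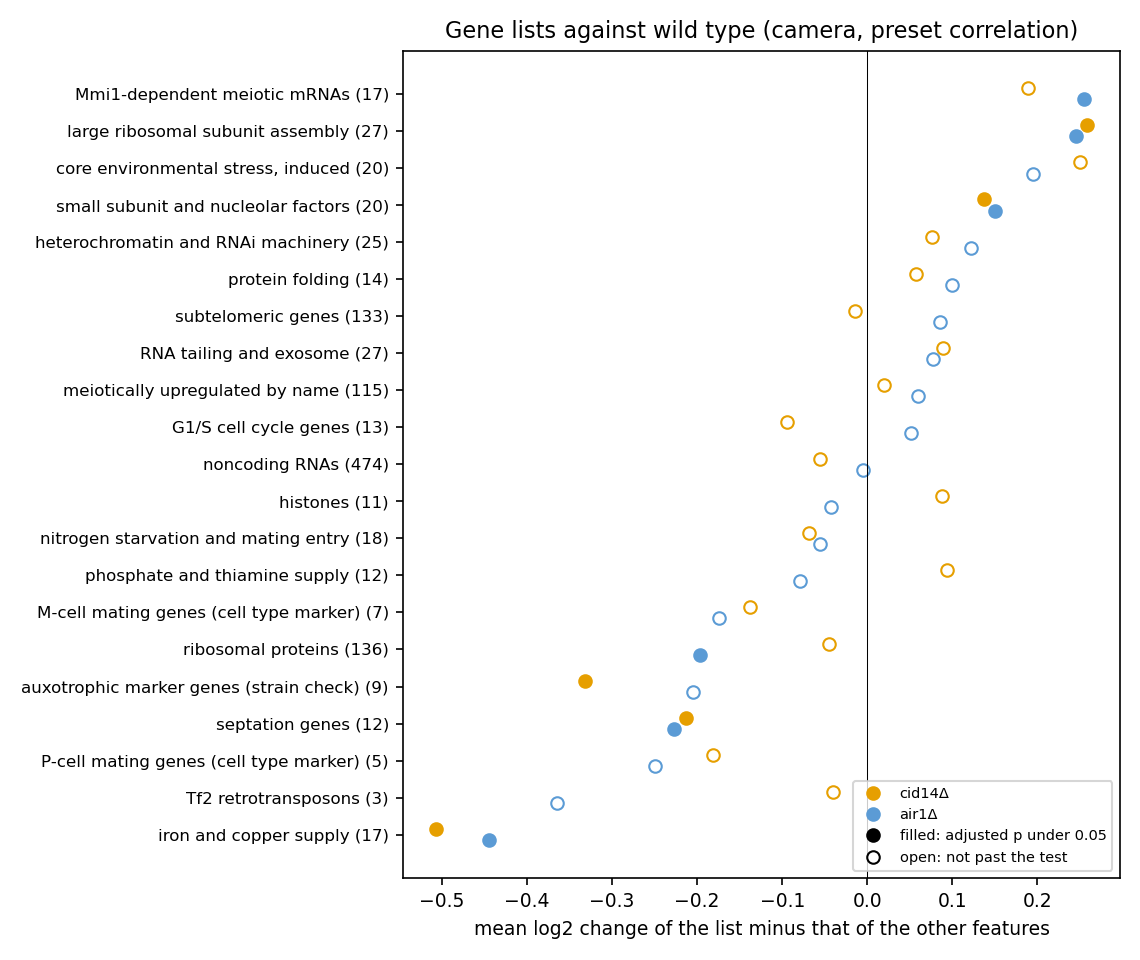
The mean log2 change of each gene list minus that of the other features (horizontal axis) is plotted for cid14delta and air1delta against wild type, with the number of members in brackets; filled points passed the camera test with the preset correlation, and 0 passed with an estimated correlation. Large subunit assembly genes lie at 0.26 and 0.25. Iron and copper supply genes lie at -0.51 and -0.44, and at -0.13 and -0.07 without wild type replicate 2, an array that both comparisons share. Ribosomal protein genes lie at -0.20 in air1delta (-0.06 after quantile normalization) and at -0.04 in cid14delta (0.06 after quantile normalization, the opposite sign).

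Where the mutants differ from each other was addressed by comparing air1delta with cid14delta, a test of the difference between their effects in which the wild type cancels. Apart from the deleted genes, the largest differences admitted by the rule were higher values in air1delta of aes1 (1.81 ± 0.16, adjusted p = 0.0133), SPBC1271.07c (1.66 ± 0.12), SPBPB21E7.08 (1.33 ± 0.10), wtf13 (SPCC162.04c, 1.30 ± 0.25), the G protein subunit gene gnr1 (SPCC1020.09, 1.20 ± 0.24) and sqs2 (1.19 ± 0.09). Lower in air1delta were SPAC4H3.08 (-1.66 ± 0.12, adjusted p = 0.0102), SPAC22A12.17c (-1.56 ± 0.16), SPAC212.04c (-1.37 ± 0.13), SPAC806.11 (-1.25 ± 0.18) and the cytochrome c oxidase subunit gene cox8 (SPAC24C9.16c, -1.21 ± 0.25). SPAC212.08c was lower as well (-1.52, a lower bound in size, adjusted p = 0.0451), with air1delta at the level of a deleted gene.

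Between the mutants limma called 549 features (10.01%), 302 higher and 247 lower in air1delta, with 16 higher and 16 lower by at least 1 on the log2 scale; 1748 passed an unadjusted p of 0.05. The split turned to 255 higher and 279 lower after quantile normalization and to 236 and 258 after a trend with gene length was removed. The groups did not overlap for 65.2% of features, where chance gives 33.3% if no difference runs across whole arrays. The mutants came from different array series, so the design does not separate series from strain here either. The count was 72 with the replicate number as a block and 68 with the shared day as a block. It was 2 without cid14delta replicate 1, 2 without cid14delta replicate 2, 4 without air1delta replicate 1 and 6 without air1delta replicate 2. After quantile normalization gnr1, clr3, mek1, rrp1, rrp9 and adg2 no longer passed the test between the mutants. The shared-day block lost 35 of 52 named calls, rps3002 and SPNCRNA.126 among them. With the replicate number as a block 33 of 52 named calls were lost. Those still past the test were cid14, air1, aes1, SPBC1271.07c, SPBPB21E7.08, sqs2, SPAC4H3.08, SPAC22A12.17c, SPAC212.04c, csl4, stc1, rps2602, rpl2002, rps3002, SPNCRNA.410, SPNCRNA.126, tgp1, mam3 and agn1.

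Ribosomal protein genes were the 1 list that passed between the mutants, and they were lower in air1delta. Of 136, 0 were higher, 12 lower and 124 did not pass (0 and 11 adjusted over the list alone), with rps2602 at -1.01 ± 0.10, rps3002 at -0.70 ± 0.08, rpl2002 at -0.53 ± 0.06 and rpl3401 at -0.49 ± 0.06. Their shift against the other features was -0.15 (adjusted p = 3.59e-05, and adjusted p = 0.723 with an estimated correlation), and after quantile normalization it was -0.11 (adjusted p = 0.00602). With the replicate number as a block the adjusted p was 2.89e-05, and with 1 array left out it was at most 0.0117 (without air1delta replicate 2, shift -0.12). With fry, which does not compare with other genes, the call was lost (adjusted p = 0.133).

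The RNA tailing and exosome list held csl4 (0.72 ± 0.07), higher in air1delta, and the uridylyltransferase gene cid1 (-0.51 ± 0.07), lower (2 and 1 adjusted over the list alone; list adjusted p = 0.798). Of the heterochromatin and RNAi genes, stc1 (0.92 ± 0.09), arb1 (0.45 ± 0.09) and clr3 (0.26 ± 0.06) were higher and 2 lower, among them epe1 at -0.37 ± 0.06 (3 and 3 adjusted over the list alone; list adjusted p = 0.676). Of the subtelomeric genes 12 were higher and 2 lower (12 and 2 adjusted over the list alone; list adjusted p = 0.0873), with SPBPB21E7.09 at 0.56 ± 0.07. Of the noncoding RNAs 21 were higher and 16 lower (14 and 10 adjusted over the list alone; list adjusted p = 0.403), with SPNCRNA.410 at 1.25 ± 0.15 and SPNCRNA.503 at -0.53 ± 0.06. Of the G1/S genes ctp1 (0.53 ± 0.06), cdc18 (0.41 ± 0.08) and suc22 (0.37 ± 0.07) were higher and 0 lower (4 and 0 adjusted over the list alone; list adjusted p = 0.0873). Of the phosphate and thiamine genes tgp1 (-0.71 ± 0.12) and bsu1 (-0.38 ± 0.08) were lower and 0 higher (0 and 3 adjusted over the list alone; list adjusted p = 0.246).

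Of the large subunit assembly genes, rrp1 (0.28 ± 0.06) was higher in air1delta and 0 lower (0 and 0 adjusted over the list alone; list adjusted p = 0.973). Of the small subunit and nucleolar factors, dim1 (0.75 ± 0.16) and rrp9 (0.25 ± 0.06) were higher and utp10 (-0.31 ± 0.05) lower (2 and 1 adjusted over the list alone; list adjusted p = 0.973). Of the Mmi1-dependent mRNAs, mek1 (0.49 ± 0.10) and mug8 (0.41 ± 0.08) were higher and 0 lower (3 and 0 adjusted over the list alone; list adjusted p = 0.622), and of the mug and meu genes 5 were higher and 6 lower (5 and 6 adjusted over the list alone; list adjusted p = 0.793). Of the nitrogen starvation genes, isp6 (0.63 ± 0.08) and spk1 (0.58 ± 0.09) were higher and mam2 (-0.31 ± 0.07) lower (2 and 1 adjusted over the list alone; list adjusted p = 0.798). Of the M-cell markers, mfm2 (at least 1.00, cid14delta at the level of a deleted gene) was higher and mam3 (-0.73 ± 0.09) and mam2 lower (1 and 2 adjusted over the list alone; list adjusted p = 0.622). Of the septation genes, agn1 (0.54 ± 0.06) was higher and adg2 (-0.32 ± 0.07) lower (1 and 2 adjusted over the list alone; list adjusted p = 0.798), and of the histones hht3 (-0.40 ± 0.06) was lower (0 and 1 adjusted over the list alone; list adjusted p = 0.253).

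The comparison of the mutants gave 0 calls among P-cell markers (list adjusted p = 0.798), stress genes (0.798), protein folding genes (0.403) and iron and copper genes (0.946), also adjusted over the list alone. The auxotrophic marker genes gave 0 calls and 5 higher adjusted over the list alone (list adjusted p = 0.276), with his5 at 0.46 ± 0.11 (adjusted p = 0.0536). The Tf2 retrotransposons gave 0 calls and 2 lower adjusted over the list alone (list adjusted p = 0.253), with Tf2-13 at -0.52 ± 0.12 (adjusted p = 0.0536). Median and mean differed in sign for the RNA tailing, assembly, stress, M-cell, P-cell and septation lists, and the test pointed down against a positive median and mean for the small subunit and the iron and copper lists.

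The mutants' effects were also set side by side against the wild-type arrays they share. Higher in both were 187 features, against 43.1 for independent lists, among them ftm4, SPCC191.05c, SPCC18B5.02c and sqs2. Lower in both were 130, against 20.7, among them aes1, SPNCRNA.366, gdh2 and SPAC11D3.18c. Unchanged strains simulated against the same wild-type arrays shared 0 calls in 100 draws, and neither value takes account of both the shared arrays and the effects. The overlaps rest on the 475 cid14delta calls made without a block. With the replicate number as a block cid14delta had 179 calls, and the overlaps were not recounted with it. The features called in both with opposite signs were 3: lsm6, atp14 and SPBPB21E7.08. Across features, which are not independent replicates, the log2 changes correlated at r = 0.597 as deposited. Simulated unchanged strains gave a mean r of 0.506 and a highest value of 0.59. After quantile normalization the observed r was 0.567, below that highest value, though the simulated strains were not normalized in that way. The covariance as deposited was 0.0576 against 0.0118 simulated, and 69.8% of features had the same sign against 66.6%. No array-wide difference was simulated, while array medians were 9.21 in wild type and 9.27 to 9.29 in the mutants. A difference common to both mutants can raise the share of equal signs and, where it varies with intensity, r and the covariance. The excess over the simulation is therefore not assigned to the deletions. With a separate wild-type array for each mutant r was 0.399 and 0.367, and 2 wild-type arrays cannot be split further with 2 on each side. With 1 array left out r ran from 0.546 (without cid14delta replicate 2) to 0.685 (without wild type replicate 1), and it was 0.569 and 0.567 without air1delta replicate 1 and replicate 2.

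**Figure D3:**
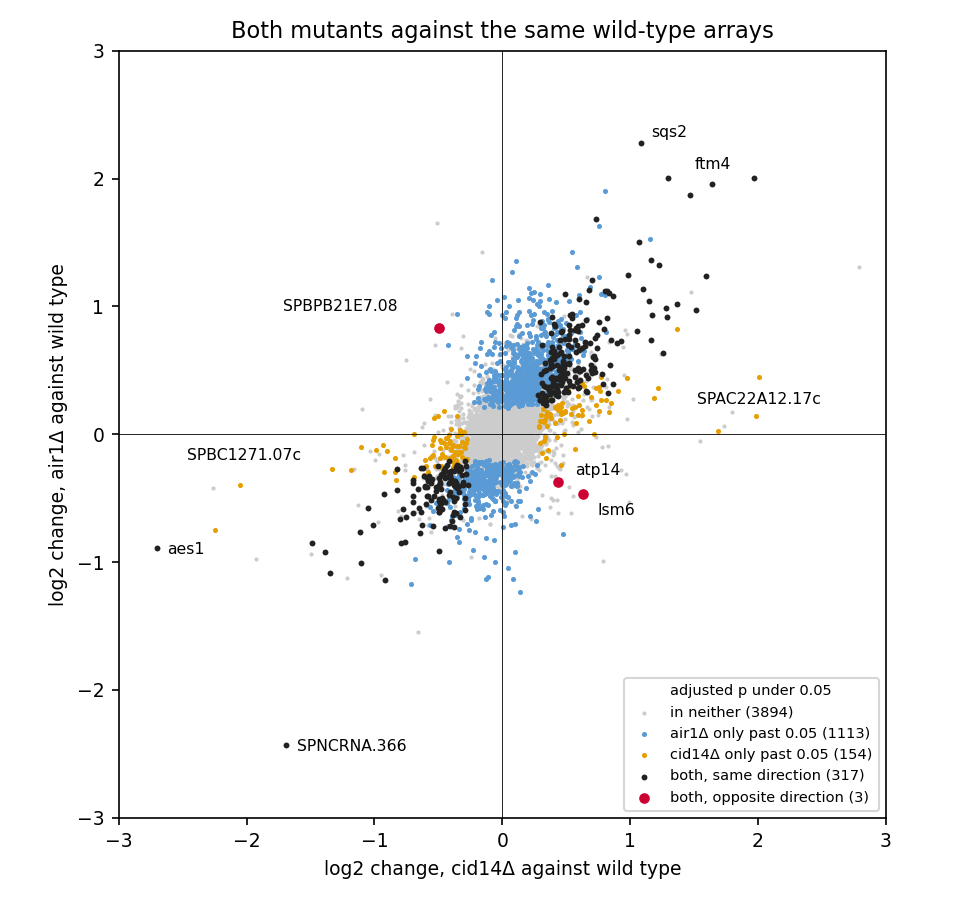
Each point is 1 feature, with its log2 change in cid14delta (horizontal axis) and in air1delta (vertical axis) against the same wild-type arrays, coloured by which limma tests it passed; the deleted genes are not drawn. Features called in both with the same sign, in the fits without a block (187 higher, 130 lower), lie along the rising diagonal, and lsm6, atp14 and SPBPB21E7.08 lie in the opposite quadrants.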

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

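The look at these features and the tests on the assembly genes and on growth rate were chosen only after the results were seen; the quantile test of the ribosomal protein genes was planned. The effects of the mutants differed in sign, each past limma's test, for 3 genes. The Lsm complex gene lsm6 was 0.63 ± 0.09 in cid14delta and -0.47 in air1delta (adjusted p = 0.0273 and 0.0228), a difference of -1.10 (adjusted p = 0.0133). The ATP synthase subunit gene atp14 was 0.44 and -0.37 (adjusted p = 0.0441 and 0.0349), a difference of -0.81 (adjusted p = 0.0188). The subtelomeric SPBPB21E7.08, next in number to SPBPB21E7.07 (aes1), was -0.49 and 0.83 (adjusted p = 0.0421 and 0.00893), a difference of 1.33 (adjusted p = 0.0102). Each strain had n = 2 arrays, and the array series cannot be told apart from the strain in these differences. Without 1 array of a mutant, 2 (cid14delta replicate 1), 2 (cid14delta replicate 2), 4 (air1delta replicate 1) or 6 (air1delta replicate 2) features passed between the mutants.

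The ribosomal protein genes also differed between the mutants as a list, with a shift of -0.15 (adjusted p = 3.59e-05, and adjusted p = 0.723 with an estimated correlation). In air1delta against wild type they lay below the other features while the large subunit assembly genes lay above them. An intensity-dependent trend between arrays may account for the ribosomal protein shift, since it went from -0.20 (adjusted p = 1.18e-06) to -0.058 (adjusted p = 0.39) after quantile normalization, although the difference between the mutants stayed at -0.11 (adjusted p = 0.00602). The same trend was argued against for the assembly genes, whose shift was 0.32 after quantile normalization (adjusted p = 3.77e-07). A common change in growth rate would move both lists one way; the values as deposited opposed each other (-0.20 for the ribosomal proteins), but this stays open because the ribosomal protein call was lost after quantile normalization. An effect of the deletion of air1 and the array series stay open too, since no series held both air1delta and wild type.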

How the results depend on the processing

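The shared-day block, the filter at the level of the deleted genes, the removal of a gene-length trend and the alternatives for the lists between the mutants were chosen only after the data were seen. Pairing by replicate number as a block in 6 arrays gave 179 features in cid14delta against 475, and 72 between the mutants against 549; in the 4 paired arrays it gave 1. The shared-day block gave 180 and 68. Both blocks left the air1delta count within 1.5 times of 1434 (1121 and 1078), and the replicate block changed no list call, between the mutants included (ribosomal proteins, adjusted p = 2.89e-05). Between the mutants the subtelomeric list was gained without cid14delta replicate 1 (shift 0.14, adjusted p = 0.0324). Fewer arrays set the spread in the 4-array fits, 69 in cid14delta and 870 in air1delta. An ordinary two-sample test without shrinkage called 0 in both, where 1039 and 1396 passed an unadjusted p of 0.05 and limma called 475 and 1434. A change of at least 1 on the log2 scale left 40, 65 and 32 by construction. Leaving out the lowest 0.25 of features gave 841 between the mutants; the cause was not tested. With 1 array left out, the lone array being assumed to vary like the other strains, the counts were 1 to 338 in cid14delta (338 without wild type replicate 1, 46 without wild type replicate 2, 1 without either cid14delta array), 273 to 952 in air1delta and 2 to 6 between the mutants. Of the 475, 403 remained called after median centring and 303 after quantile normalization, and of the 1434, 1173 and 1048.

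Lists past the test numbered 5 in cid14delta and 6 in air1delta. Without the lowest 0.25 of features the Mmi1-dependent list kept fewer than the 3 members needed. It therefore dropped out of the air1delta count there without a test. They were 0 and 0 with an estimated correlation, where limma's camera also gave 0 and 0 at an unadjusted p under 0.05, 8 in cid14delta after quantile normalization (gained: ribosomal proteins, histones, stress and P-cell genes; lost: iron and copper), 3 in air1delta without the lowest 0.25 of features, 4 to 7 and 3 to 8 with 1 array left out, and 3 in air1delta without wild type replicate 2; the cause was not tested. The correlation of the mutants' effects was 0.567 after quantile normalization, 0.399 and 0.367 with separate wild-type arrays, and 0.546 to 0.685 with 1 array left out. Separate arrays remove the error of a single shared array, but not a difference common to both wild-type arrays. The ribosomal protein list in cid14delta turned from a shift of -0.044 (adjusted p = 0.156) to 0.055 after quantile normalization, where it passed (adjusted p = 0.0339). In air1delta the folding and P-cell lists were gained there. Medians of lists not past camera as deposited also turned under another scaling: heterochromatin, mug and meu, noncoding, folding and phosphate in cid14delta; mug and meu, noncoding, histones, folding, nitrogen and G1/S in air1delta; mug and meu, noncoding, M-cell and P-cell between the mutants. Of lists not past camera, fry passed P-cell genes in both mutants (adjusted p = 0.0236), phosphate in cid14delta (0.0295), heterochromatin (0.0471), auxotrophic markers (0.0471) and G1/S (0.0236) in air1delta, and phosphate (0.0356) and G1/S (0.00883) between the mutants. Among named genes signs turned where the value was not past the test: Tf2-11 in cid14delta (-0.018 without wild type replicate 1, -0.045 without cid14delta replicate 2, range -0.045 to 0.19), cid14 in air1delta (-0.026 after quantile normalization), Tf2-10 in air1delta (0.020 without wild type replicate 2, range -0.54 to 0.020) and Tf2-10 between the mutants (-0.0083 after quantile normalization, -0.12 without cid14delta replicate 2, -0.15 without air1delta replicate 2, range -0.15 to 0.23); the cause was not tested. Of named called genes, 195 of 211 stayed past the test after median centring, 174 after quantile normalization and 136 with the replicate block, and 78 were lost with the shared-day block. With 1 array left out 546 of these calls were lost and 298 stayed, counted once per array, and the ordinary two-sample test lost all 159 calls it was run on. At or below 4.90, the level of a deleted gene, signal over background limits what can be read.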

Other observations

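The gene families described here, the features named with them and all tests below were chosen only after the data were seen. For gene length and background level the criteria were written before the outcome of the test. Families were taken as symbols with a shared root and at least 8 members, 75 in number, and none passed camera with an estimated correlation (adjusted p = 0.766 for those described below, apart from 0.768 for cwf and 0.812 for nup in cid14delta). They were not run with arrays left out, and camera with the preset correlation gave the other adjusted p-values. The families described are a selection of those past camera with the preset correlation. Others past it were rrp, utp and nop, higher in both mutants. In cid14delta mrp was also higher, and ade and erg were lower. In air1delta prp, dbp and trm were also higher, and rps, rpl, rga and alg were lower. The wtf genes, a family of meiotic drivers with similar copies that can cross-hybridise, had positive changes for all 24 members in air1delta, with a median of 0.49 (0.42 after median centring, 0.32 after quantile normalization). Of them 14 rose and 0 fell (adjusted p = 8.38e-05), among them wtf25 (1.37), wtf7 (0.70 ± 0.11) and wtf23 (0.55 ± 0.10). In cid14delta their median was 0.08, and -0.01 after quantile normalization, with 2 higher (adjusted p = 0.28). For wtf23 and wtf9 the difference between the mutants was 0.59 (adjusted p = 0.032) and 0.53 (adjusted p = 0.029). The splicing factor genes named cwf had 11 of 22 higher and 0 lower in air1delta (median 0.35, adjusted p = 0.00175), and 5 higher and 0 lower in cid14delta (median 0.26, adjusted p = 0.00272). Among them cwf12 was 1.02 ± 0.08 in air1delta and 0.27 in cid14delta (adjusted p of the difference 0.017), and cwf26 was 0.86 and 0.40.

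The arginine biosynthesis genes named arg fell in both mutants, 7 of 10 in cid14delta (median -0.55, adjusted p = 8.38e-05) and 6 in air1delta (median -0.30, adjusted p = 0.0095), with arg4 at -0.64 and -0.61 and arg12 at -0.70 and -0.53. The ATP synthase genes named atp had 4 of 18 higher and 0 lower in cid14delta (median 0.23, adjusted p = 0.00206), among them atp5 (0.65 ± 0.10) and atp11 (0.49 ± 0.07). In air1delta 5 were higher and 1 lower, atp5 among them at 0.46, and the family did not pass (median 0.14, adjusted p = 0.36). The nucleoporin genes named nup had 7 of 20 lower and 0 higher in air1delta (median -0.17, adjusted p = 0.00456), among them nup85 (-0.44 ± 0.08) and nup186 (-0.33 ± 0.06), and 0 higher and 0 lower in cid14delta (median -0.058, adjusted p = 0.2). Heat shock genes named hsp had 7 of 12 higher and 0 lower in air1delta (median 0.62, adjusted p = 0.0227), with hsp3101 at 0.74 in air1delta and 1.16 in cid14delta. In cid14delta 3 were higher and 0 lower, 11 of 12 changes were positive, and the family did not pass as deposited (median 0.20, adjusted p = 0.0615), but passed after quantile normalization (adjusted p = 0.0175) and with fry (adjusted p = 0.0135). With fry wtf in cid14delta (adjusted p = 0.0418) and atp in air1delta (adjusted p = 0.0466) passed too, and cwf in cid14delta did not (adjusted p = 0.0817). Medians of the arg, atp, nup, cwf and hsp families given here had the same sign under both other scalings. The feature SPBPB2B2.03c, which was not matched to the reference table, rose by 1.97 ± 0.27 in cid14delta and by 2.01 ± 0.27 in air1delta (adjusted p = 0.0241 and 0.011). The subtelomeric helicase gene tlh1 fell by 0.93 ± 0.15 in cid14delta and was -0.08 in air1delta (adjusted p of the difference 0.034).

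More features were called in air1delta (1434) than in cid14delta (475). Whether the array series alone made all air1delta calls was not settled. Calls were remade against 1 wild-type array each, 534 and 951 of them. The other wild-type array served cid14delta, which shared the wild type's series. Of these calls 83.7% and 79.9% had the same sign in cid14delta, against 64.7% and 65.7% of all features. A difference common to both wild-type arrays would also give equal signs, and it was not removed. Array medians were 9.21 and 9.21 in wild type and 9.27 to 9.29 in the mutants. A gene length bias was argued against as the whole source of the excess, because removing a trend with gene length left 1359 and 468 calls, a ratio of 2.90, although change and length did correlate across genes (Spearman's rho -0.195 in air1delta and -0.126 in cid14delta). The design by itself does not separate the array series from the deletion in any air1delta call, because no series held both air1delta and wild type. The 349 air1delta calls that also separate the mutants are among them.

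The neighbour of the deleted air1 gene, usp103, which encodes a U1 snRNP protein, rose by 1.11 ± 0.08 in air1delta (adjusted p = 0.00486) and was 0.25 in cid14delta (adjusted p = 0.0986). A general effect of a deletion on the nearest genes at both loci, as large as that on usp103, was argued against. In cid14delta the nearest neighbours of cid14 were pfs2 (0.26 ± 0.06, adjusted p = 0.0676) and gms2 (0.23 ± 0.09, adjusted p = 0.16). They were matched or exceeded in size by at least 25.9% of all features. A smaller effect was not excluded, since these and the next features, sif3 (0.11) and miy1 (0.24), were all positive. An effect of the air1 deletion on its own neighbour is a candidate explanation, with a difference between the mutants of 0.86 (adjusted p = 0.0133), while the neighbour on the other side, ilv1, was -0.10. The array series stays open as well and cannot be told apart from it, although 0.785% of features changed as much in air1delta. Whether the deletion construct reached usp103 was not tested.

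A gain of chromosome III throughout the cid14delta cultures was argued against, since the median change of its features exceeded the higher of the other chromosomes by 0.0044. A gain in a small share of the cells was not excluded, since it would move the median of a whole culture little. Calls whose mean over all arrays lay at or below the level of the deleted genes were 3.58% of the cid14delta calls. Calls of that kind were too few to account for the others. This share leaves out calls such as SPNCRNA.366 and mfm2, where cid14delta lay at that level but the mean over all arrays did not. The share of calls with either compared strain at that level was not tested.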
